A study of Mus musculus with 12 samples.

How the data were processed

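Raw counts per Ensembl gene were used as deposited, as whole numbers with 1 column per library. The TPM values, transcript levels scaled by gene length, were used as deposited by the authors, with each column scaled to the same sum. Per the labels the authors used STAR 2.7.8a, Picard 2.9.0, R 4.1.12 and DESeq2 1.34.0. The labels list the builds GRCm38 and mm9 without their roles, and the counting program is not given in the sources used here. Dividing counts by TPM gave 1 implied length per gene in every library, and for 10160 of 10308 genes (98.6%) it lay within 1% of the summed exon length in GENCODE M21 on GRCm38. Positions, chromosomes and gene types were therefore taken from GENCODE M21 by gene ID.

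The counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr over the 4 groups, which left 15801. Library sizes were scaled with TMM factors. A model with 1 mean per group was fitted over the 12 libraries, with 8 residual degrees of freedom and robust quasi-likelihood dispersion. The 6 comparisons taken from it were Fes-/- against wild type under PBS, under LPS and averaged over both, LPS against PBS in each genotype, and the difference of the LPS effects (interaction). Each was a two-sided F test, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method and called under 0.05. Where an adjusted p is given for a gene without a tool, it comes from edgeR, and where it is given for a list, from camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists in a comparison. Camera compares a list with all other genes.

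The 36 gene lists, with 725 entries, were fixed from general knowledge of macrophage biology. They cover 697 different genes, of which 632 were tested. Genes to be named were Fes, the 10 highest rises and 10 largest falls among called genes with at least 5 CPM in some compared group and replicates that did not overlap, leaving out unnamed gene models, and up to 4 members with the smallest p per list. The comparisons, groups, tests, lists, naming rule and first alternatives were chosen before the data were examined. The planned list tests were camera with the preset correlation, camera with an estimated correlation and the fry test of limma. Setting the estimated correlation among the alternatives, and the counts without genes of chromosome 7, were added after the data were seen.

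The alternatives were DESeq2 1.42.0 with its Wald test, RLE factors, no factor beyond the library total, no filter, a filter of 1 CPM in at least 3 libraries, the 6 libraries of a comparison alone, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and each library left out in turn. Leaving out a library leaves 2 in its group, and the dispersion is pooled over all groups. Other splits of the samples were fitted with the same model. Transcripts of called genes off chromosome 7 were compared with the transcriptome by BLAST 2.17.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

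The test was checked on counts simulated for all 12 libraries from the mean levels and dispersions of the real data. Between genotypes under PBS, 50 genes were changed at each of 4 sizes. The test recovered 24 of 50 genes (48%) at 1.414-fold, 47 of 50 (94%) at 2-fold and 50 of 50 at 4-fold and 8-fold. Of its 175 calls, 4 were false (2.29%). Of 200 random lists with no change, 8 had a camera p under 0.05. Genes were simulated independently of each other, so this does not check camera on lists whose genes move together. With 175 calls the simulation had a looser cut-off on p than the genotype comparisons, where recovery may be lower. Reads, exons and variants were not analysed here, and some genes that met the naming rule are not reported here.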

Results

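Gene expression was measured by poly-A-enriched RNA sequencing in mouse bone-marrow-derived macrophages, cells grown out of marrow with macrophage colony-stimulating factor (M-CSF). The macrophages carried either the intact Fes gene (Fes+/+, wild type) or a targeted Fes allele on both chromosomes (Fes-/-). FES is a cytoplasmic tyrosine kinase found mainly in myeloid cells. Cells of each genotype received PBS or 1 µg/mL lipopolysaccharide (LPS), a bacterial wall component sensed through TLR4, for 4 hours. The treatment description calls the PBS cells untreated. Each of the 4 groups held 3 libraries, and all 12 carried 1 batch date. The series title concerns the priming of CD8+ T cells by Fes-deficient macrophages and anti-tumour immunity, so genes of cytokine output, antigen presentation and co-stimulation were examined by name.

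The 12 libraries held 61016254 to 101027166 counts each. In replicates 1, 2 and 3 the totals were 76617456, 63932110 and 65087720 for wild-type PBS and 61016254, 66171038 and 66427038 for wild-type LPS. They were 61682213, 70038994 and 62026557 for Fes-/- PBS and 101027166, 77752777 and 64756607 for Fes-/- LPS. Of 55487 genes in the table, 28358 had a count in some library and 15801 were tested. Fold changes are log2 with their standard error (SE), levels are CPM (counts scaled to a common library size after TMM) as mean ± SD of 3 libraries, and intervals cover 95%. Intervals on counts and lower limits cover counting error only, since the labels describe no molecular identifiers.

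The first question was how macrophages without intact Fes differ from wild type at rest. Fes itself (ENSMUSG00000053158, GRCm38 chromosome 7, 80377756 to 80387946) fell from 179 ± 10.2 CPM in wild type to 68.6 ± 2.05 CPM in Fes-/- macrophages under PBS (n = 3 each), which left 38.3% of the wild-type level. Its log2 change was -1.38 ± 0.07 (adjusted p = 6.16e-08). Its neighbour Furin, which encodes a proprotein convertase that trims TGF-beta and other precursors, fell from 130 ± 16.7 to 66.2 ± 8.63 CPM (-0.98 ± 0.11, adjusted p = 0.000623). Man2a2, the other adjacent gene, encodes a Golgi mannosidase of N-glycan processing and fell from 96.8 ± 23.2 to 30.3 ± 2.82 CPM (-1.68 ± 0.17, adjusted p = 0.000517). Hddc3, a nearby gene for a nucleotide pyrophosphohydrolase, rose from 2.73 ± 0.158 to 6.67 ± 0.421 CPM (1.29 ± 0.18, adjusted p = 0.00569). In each of these 4 genes all 3 Fes-/- libraries lay on 1 side of all 3 wild-type libraries.

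Farther along chromosome 7, Alg8, which encodes a glucosyltransferase for N-linked glycans and starts at 97.37 Mb, fell from 28 ± 2.87 to 13.7 ± 1.22 CPM (-1.03 ± 0.11, adjusted p = 4e-04). Fah at 84.59 Mb, the last enzyme of tyrosine breakdown, rose from 3.85 ± 1.15 to 11 ± 3.78 CPM (1.52 ± 0.24, adjusted p = 0.0308). Amd2 (ENSMUSG00000063953, chromosome 10, 35708675 to 35711892) rose from 0.26 ± 0.0997 to 10.7 ± 1.37 CPM (5.38 ± 0.26, adjusted p = 3.43e-08). Its transcript matched Amd1, the gene for the polyamine enzyme S-adenosylmethionine decarboxylase, at 99.6% over 3202 bp, so its counts are uncertain. Further called genes were chosen after their values were seen. Dgat2, a triglyceride synthesis enzyme at 99.15 Mb, had 2.57 against 0.62 CPM, and Fsd2 had 2 counts in Fes-/- against 111 in wild type. Gm44751 rose (2.62 ± 0.12), Gm26862 had 419 counts against 1, and Gm35082 had 281 counts against 0, at least 98-fold higher against a limit of 3 counts over the group. Gm44075, a 216-bp gene model on chromosome 6, had 454 counts against 0 (at least 155-fold). It matched Trim21 at 97.7% over 215 bp and is likewise uncertain.

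By the edgeR quasi-likelihood test 13 of 15801 genes were called between genotypes under PBS, 8 higher and 5 lower in Fes-/- macrophages, and 605 had an unadjusted p under 0.05. The interval lay within 2-fold either way for 12298 genes (77.8%). DESeq2 called 33 genes, which included all 13, and the test without a filter on low counts called 315. The call of Fah ended on leaving out wild-type PBS 1 or 3, Fes-/- PBS 1, any wild-type LPS library or Fes-/- LPS 1 (adjusted p = 0.06 to 0.187), and that of Hddc3 without wild-type PBS 3 (0.0573). Fah was at 0.494 with the 6 PBS libraries alone.

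The same comparison was made in stimulated macrophages, where cytokine and antigen-presentation genes are active. Under LPS, Fes fell from 162 ± 9.77 CPM in wild type to 33.8 ± 1.16 CPM in Fes-/- macrophages, or 20.9% (-2.26 ± 0.07, adjusted p = 3.23e-10). Furin, itself an LPS-induced gene, reached 752 ± 76.4 CPM in wild type and 262 ± 6.78 CPM in Fes-/- macrophages (-1.52 ± 0.11, adjusted p = 4.66e-06). Man2a2 fell from 42.8 ± 9.38 to 14.3 ± 0.469 CPM (-1.58 ± 0.17, adjusted p = 0.000993). Blm, a RecQ DNA helicase gene next to Furin, fell from 11.4 ± 1.92 to 4.34 ± 0.695 CPM (-1.38 ± 0.14, adjusted p = 0.000126), and Unc45a, a myosin chaperone gene, from 31.1 ± 1.81 to 15.5 ± 0.616 CPM (-1.0 ± 0.09, adjusted p = 4.38e-05). Alg8 fell as under PBS (-0.94 ± 0.11, adjusted p = 0.000928).

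Tsku, which encodes the secreted protein tsukushi and starts at 98.35 Mb, rose from 1.77 ± 0.885 to 11.7 ± 1.13 CPM (2.73 ± 0.27, adjusted p = 0.000158). Inppl1, which encodes the lipid phosphatase SHIP2 at 101.8 Mb, rose from 332 ± 39.7 to 500 ± 38.3 CPM (0.59 ± 0.09, adjusted p = 0.0172). Hddc3 (2.06 ± 0.21, adjusted p = 0.000187), Fah (1.59 ± 0.26, adjusted p = 0.0296) and Ngrn, a gene of mitochondrial ribosome assembly (0.79 ± 0.13, adjusted p = 0.0325) also rose. Amd2 rose by 4.80 ± 0.27 (adjusted p = 1.3e-07), again with the uncertainty of its copy. Chosen after their values were seen, Trim68 rose by 0.89 ± 0.14, Gm44751 by 2.74 ± 0.11 and Gm35363 by 2.04 ± 0.33. Gm26862 had 373 counts against 0, and the uncertain Gm44075 had 4842 counts against 0, at least 1260-fold higher.

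**Figure D1:**
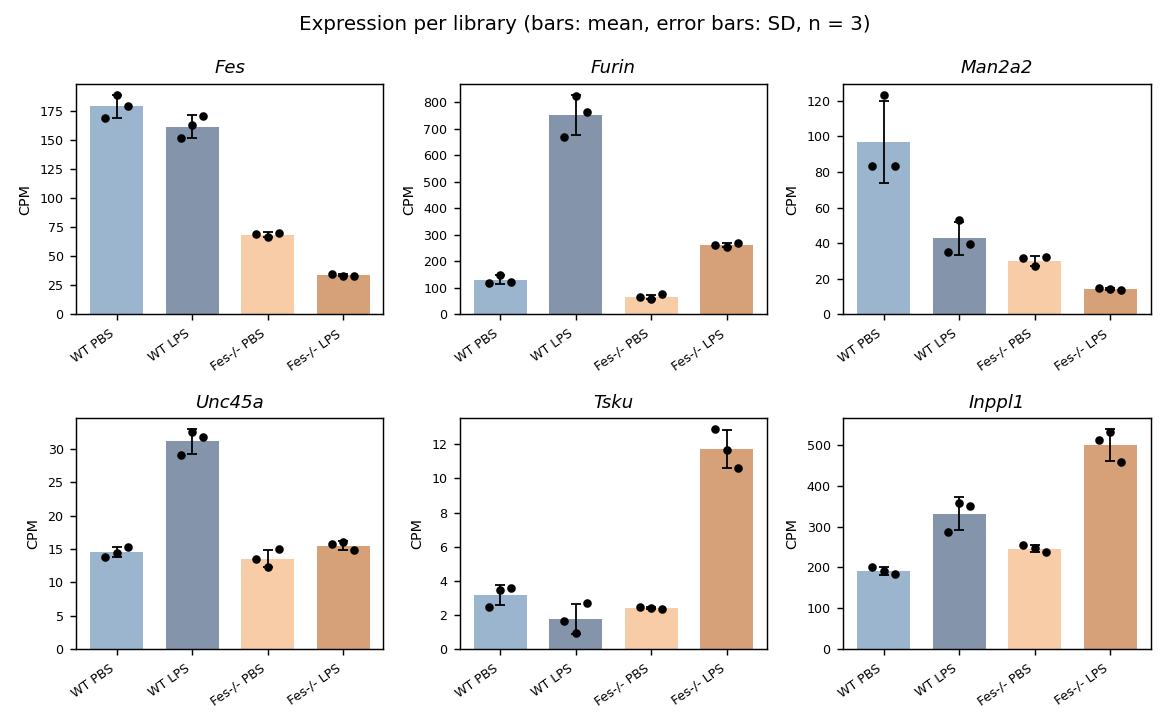
CPM of Fes, Furin, Man2a2, Unc45a, Tsku and Inppl1 in wild-type and Fes-/- macrophages under PBS and LPS; bars are means of 3 libraries, error bars SD and points single libraries. Furin reached 752 CPM in wild type and 262 CPM in Fes-/- macrophages under LPS, and Tsku 1.77 and 11.7 CPM.

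The test called 17 genes between genotypes under LPS, 11 higher and 6 lower in Fes-/- macrophages, with 1030 at an unadjusted p under 0.05 and 11711 genes (74.1%) with an interval within 2-fold. DESeq2 called 37 and shared all 17, and 358 were called without a filter. Leaving out 1 library ended the call of Fah (wild-type LPS 1, 2 or 3 or Fes-/- LPS 1 or 3, adjusted p = 0.103 to 0.229), of Ngrn (wild-type PBS 3, any wild-type LPS library, Fes-/- PBS 1 or Fes-/- LPS 1 or 2, 0.0576 to 0.242), of Inppl1 (wild-type LPS 1, Fes-/- LPS 1 or 2, 0.0865 to 0.135) and of Trim68 (wild-type LPS 1 or 2, Fes-/- LPS 1, 0.146 to 0.164). With the 6 LPS libraries alone Ngrn (0.161), Inppl1 (0.0756) and Trim68 (0.22) were not called, and on log2(TPM + 1) Fah (0.0512) and Trim68 (0.057) were not.

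Cytokine, co-stimulation and MHC class I genes were read next, and those named here were not called between genotypes. Under LPS, Il12b, which encodes the p40 chain of IL-12 and IL-23, averaged 476 ± 288 CPM in wild type and 1190 ± 580 CPM in Fes-/- macrophages (1.32 ± 0.52, adjusted p = 0.738). Il6 averaged 1250 ± 226 and 1640 ± 382 CPM (0.40 ± 0.21, interval -0.05 to 0.84, adjusted p = 0.791). Tnf averaged 2470 ± 483 and 3570 ± 1060 CPM (0.53 ± 0.40, adjusted p = 0.883), and under PBS 6.89 ± 3.31 and 11.2 ± 4.39 CPM (adjusted p = 0.975). Cd80, a CD28 ligand, averaged 26.1 ± 5.67 and 36.9 ± 10.4 CPM (adjusted p = 0.731), and Cd40 1760 ± 14.2 and 1840 ± 79.5 CPM (adjusted p = 0.948). The MHC class I genes B2m (3690 ± 107 and 3400 ± 292 CPM, -0.12 ± 0.09, adjusted p = 0.881) and H2-K1 (2410 ± 107 and 2290 ± 255 CPM, -0.07 ± 0.13, adjusted p = 0.947) had narrow errors. Tnf and Cd40 under LPS, and H2-K1, were chosen after their values were seen. In the test without a filter on low counts Il12b (adjusted p = 2.28e-35), Il6 (0.00585), Tnf (4.65e-05) and Cd80 (0.000357) were called under LPS. In the other 21 alternatives, DESeq2 among them, their adjusted p ranged from 0.419, 0.444, 0.701 and 0.235 in that order up to 1.

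**Figure D2:**
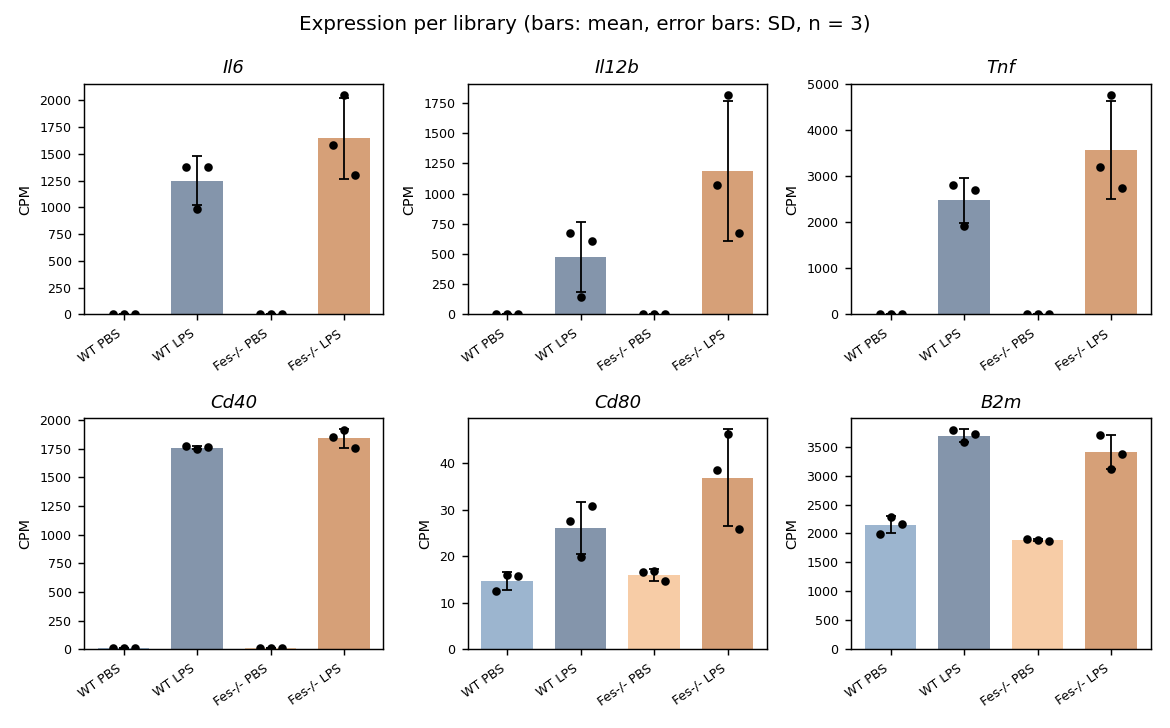
CPM of the cytokine genes Il6, Il12b and Tnf and of Cd40, Cd80 and B2m in wild-type and Fes-/- macrophages under PBS and LPS, as means of 3 libraries with SD and single libraries as points. None was called between genotypes under LPS, with Il12b at 476 CPM in wild type and 1190 CPM in Fes-/- macrophages.

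Gene lists fixed in advance were tested by camera for a shift against all other genes. Under LPS no member of the 18 NF-kB targets, 20 inflammatory cytokines, 22 chemokines, 48 interferon-stimulated genes, 22 MHC class I genes, 13 MHC class II genes or 22 co-stimulatory genes was called between genotypes by edgeR, and none when adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 3, 3, 1, 0, 1 and 3 members in that order, and DESeq2 called 0 in each list. The list tests gave adjusted p of 0.925, 0.0818, 0.0818, 0.813, 0.436, 0.558 and 0.728. All 22 MHC class I genes had an interval within 2-fold. The cytokine list was called without Fes-/- LPS 3 (0.0292), and the chemokine list without Fes-/- LPS 3, wild-type LPS 1 or Fes-/- PBS 3 (0.0251 to 0.0495). Without a filter on low counts these lists were called as well (0.0346 and 0.0357). That setting also called the single genes Cxcl1 (2.31e-18), Ifnb1 (0.000515), Osm (0.041) and Irf8 (0.0491), whose adjusted p over the other 21 alternatives ranged from 0.329 to 1.

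The 10 genes next to Fes had the smallest list p under LPS and in the averaged comparison, but not under PBS. Under LPS 1 rose, 4 fell and 5 were not called, or 1 and 5 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 4.1e-15; adjusted p = 0.000882 with an estimated correlation). Under PBS 1 rose, 2 fell and 7 were not called, or 1 and 3 adjusted over the list alone, with a median of -0.039 (camera adjusted p = 0.0011; adjusted p = 0.0959 with an estimated correlation). The 32 cell-cycle genes were shifted upward in Fes-/- macrophages, with 31 of 32 positive under LPS, a median of 0.16 and 0 members called by edgeR or DESeq2, 4 at an unadjusted p under 0.05 (camera adjusted p = 2.11e-05; adjusted p = 0.584 with an estimated correlation). Under PBS 29 of 32 were positive, with a median of 0.12 (camera adjusted p = 0.00037; adjusted p = 0.494 with an estimated correlation), and without wild-type PBS 2 the adjusted p was 0.452. The 28 lysosome genes were shifted downward, at -0.13 under PBS (camera adjusted p = 6.52e-07; adjusted p = 0.42 with an estimated correlation) and -0.091 under LPS (0.00146; adjusted p = 0.612 with an estimated correlation). For example, Ctsl, a lysosomal protease gene, averaged 1020 CPM in wild type and 790 in Fes-/- under PBS (-0.37 ± 0.10, adjusted p = 0.674), and DESeq2 called it (0.0441).

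Neutrophil and granulocyte precursor genes were lower, with a median of -0.53 under PBS (camera adjusted p = 3.08e-06; adjusted p = 0.0959 with an estimated correlation). Under LPS the median was -0.28 (0.031; adjusted p = 0.584 with an estimated correlation), and that call ended without wild-type LPS 1 or 2 or Fes-/- LPS 1 or 2 (0.0683 to 0.102). S100a9, a calprotectin subunit gene, had a log2 fold of -0.79 ± 0.17 under PBS (adjusted p = 0.218), and was called adjusted over the list alone and by DESeq2 (0.00124). Macrophage identity genes had a median of -0.15 under PBS (camera adjusted p = 0.00037; adjusted p = 0.42 with an estimated correlation). MHC class II genes had a median of -0.21 under PBS (0.00702; adjusted p = 0.567 with an estimated correlation), lost without wild-type PBS 2 (0.144) or Fes-/- PBS 2 (0.11). Their member Ctss, a protease that trims the invariant chain, averaged 2050 and 1580 CPM (-0.37 ± 0.10, adjusted p = 0.859) and was called adjusted over the list alone. With a filter of 1 CPM in 3 libraries the neutrophil call under LPS ended (0.142). LXR target genes had a median of -0.16 under PBS (0.0289; adjusted p = 0.425 with an estimated correlation), lost without wild-type PBS 2 (0.144), Fes-/- PBS 2 (0.123) or Fes-/- PBS 1 (0.0694) or with that filter (0.0516).

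Cholesterol synthesis genes had a median of 0.13 under PBS (camera adjusted p = 0.0115; adjusted p = 0.745 with an estimated correlation) and -0.11 under LPS (0.0374; adjusted p = 0.924 with an estimated correlation). The former call ended without wild-type PBS 2 (0.628) or Fes-/- PBS 2 (0.367), and the latter without wild-type LPS 2 (0.74) or Fes-/- LPS 1 (0.134) or with a filter of 1 CPM in 3 libraries (0.0808). Dendritic cell markers had a median of 0.19 under LPS (0.0374; adjusted p = 0.584 with an estimated correlation), lost without wild-type LPS 1 or 2 or Fes-/- LPS 1 or 3 (0.0716 to 0.154) or with that filter (0.11). Members called adjusted over the list alone were Ccl4 (0.54 ± 0.16) and Ccl6 (-0.53 ± 0.14) among chemokines and Cadm1 (0.25 ± 0.07) among dendritic cell markers under PBS. Under LPS they were the formyl peptide receptor Fpr2 (0.33 ± 0.09), the kinase Bcr (-0.61 ± 0.16) and the B-cell receptor component Cd79b (-0.55 ± 0.16). Over all genes, the test without a filter called Ccl4 (0.00181), Ccl6 (1.21e-05), Ctss (0.0392) and Tnf (7.94e-07) under PBS and Fpr2 (0.0241) under LPS, and over the other 21 alternatives their adjusted p ranged from 0.0657 to 1. The PBS tests of NF-kB targets, cytokines, chemokines, interferon-stimulated, MHC class I and co-stimulatory genes gave adjusted p of 0.156, 0.794, 0.155, 0.794, 0.449 and 0.597. The interferon list turned with single libraries, from a median of 0.27 without Fes-/- PBS 3 (2.58e-14) to -0.15 without Fes-/- PBS 1 (0.000146), and was 0.21 without wild-type PBS 3 (0.00139). NF-kB targets were called without wild-type PBS 3 (0.00716) or Fes-/- PBS 2 (0.0467), chemokines without wild-type PBS 3 (0.000264) or Fes-/- PBS 3 (0.00369), and MHC class I genes without Fes-/- PBS 1 (0.000273) or wild-type PBS 2 (0.00238).

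Averaged over PBS and LPS, the genotype comparison asked which differences hold with 6 libraries per genotype, from 3 mice each and fitted as independent. Libraries of 1 mouse are not independent, so the adjusted p-values of this comparison may be too small. Beyond Fes (-1.82 ± 0.05, adjusted p = 3.88e-11), Furin (-1.25 ± 0.08) and Man2a2 (-1.63 ± 0.12), the genes Blm (-1.01 ± 0.09), Alg8 (-0.99 ± 0.08) and Unc45a (-0.55 ± 0.06) fell. Hddc3 (1.67 ± 0.14), Fah (1.55 ± 0.18), Dgat2 (1.53 ± 0.15), Tsku (1.17 ± 0.18), Ngrn (0.59 ± 0.09) and Inppl1 (0.48 ± 0.07) rose. The average for Tsku joins unlike effects, since it rose under LPS only (2.73). Under PBS it had 213, 237 and 202 counts in Fes-/- libraries against 257, 300 and 320 in wild type. Unc45a was called under LPS (-1.0) but not under PBS. Aamdc, a gene linked to adipogenesis, fell by 0.74 ± 0.11, and Ramac, a subunit of the mRNA cap methyltransferase, by 0.36 ± 0.06. Off chromosome 7, the zinc-finger gene Plagl1 rose (0.91 ± 0.17, adjusted p = 0.0485) and Cd5l, which encodes a scavenger-type protein secreted by macrophages, fell (-1.09 ± 0.18, adjusted p = 0.0474). Gm43305 on chromosome 14 (-1.79 ± 0.24), Dnajb13 (-1.63 ± 0.28) and Trim68 (0.71 ± 0.10), chosen after their values were seen, were called too.

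By this test 26 genes were called, 14 higher and 12 lower in Fes-/- macrophages, with 1385 at an unadjusted p under 0.05 and 13137 genes (83.1%) with an interval within 2-fold. DESeq2 called 88 with all 26 among them, no filter gave 581, and without Fes-/- PBS 3 there were 36. Leaving out single libraries ended some calls. Plagl1 (adjusted p = 0.0696 to 0.248) and Cd5l (0.0586 to 0.214) were each lost without any of 9 libraries, and Plagl1 was not called with RLE factors (0.0531), a filter of 1 CPM in 3 libraries (0.0668) or TPM (0.161 and 0.272). Plagl1 kept its call without Fes-/- PBS 3, Fes-/- LPS 3 or wild-type LPS 3, and Cd5l without Fes-/- PBS 2 or 3 or wild-type LPS 3. Gm43305 was lost without wild-type PBS 2, Fes-/- PBS 1 or Fes-/- LPS 1 or 3 (0.063 to 0.0771). Tsku was lost without Fes-/- PBS 1, Fes-/- LPS 1 or wild-type LPS 1 (0.0536 to 0.0679), and Aamdc without Fes-/- LPS 1 (0.0548). Across lists, camera called the Fes neighbours (2.41e-12; adjusted p = 0.00183 with an estimated correlation), lysosome (3.47e-07; adjusted p = 0.388 with an estimated correlation), cell cycle (7.19e-07; adjusted p = 0.388 with an estimated correlation), neutrophil (1.47e-05; adjusted p = 0.156 with an estimated correlation), macrophage identity (0.000871; adjusted p = 0.388 with an estimated correlation) and B cell lists (0.0413; adjusted p = 0.292 with an estimated correlation). The B cell call ended without wild-type LPS 2 (0.143), Fes-/- PBS 2 (0.136), wild-type PBS 3 (0.0877) or Fes-/- LPS 1 or 3 (0.0533 and 0.0523), with DESeq2 (0.0722), with a filter of 1 CPM in 3 libraries (0.164) or without a filter (median 0.32, 0.23). MHC class II genes were not called (median -0.13, 0.0658; adjusted p = 0.682 with an estimated correlation). They were called with DESeq2 (0.0371), without a filter (0.015), with a filter of 1 CPM in 3 libraries (0.027) and without Fes-/- LPS 1, wild-type PBS 1, Fes-/- PBS 1, wild-type LPS 1 or Fes-/- PBS 3 (0.00622 to 0.0326). Of the other immune lists, not called either, chemokines (0.11) were called without a filter (0.0473) or without wild-type PBS 3, Fes-/- PBS 3 or Fes-/- LPS 3 (0.000482 to 0.0474). MHC class I genes (0.33) were called without Fes-/- PBS 1 (0.00248) or wild-type PBS 2 (0.0235), and classical activation markers (0.117) without Fes-/- PBS 3 (0.00394) or wild-type PBS 3 (0.00712). The interferon list (0.932) was called upward without Fes-/- PBS 3 (1.18e-05) and downward without Fes-/- PBS 1 (0.00671). Adjusted over the list alone, 3 lysosome, 2 neutrophil, 3 B cell, 1 macrophage identity, 1 MHC class II and 1 chemokine gene were lower in Fes-/- macrophages, and 2 dendritic cell, 1 monocyte and 1 classical activation gene higher.

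The called genes lay mostly on chromosome 7, which held 1222 of the 15801 tested genes (7.73%). Fes, Furin, Man2a2, Hddc3, Fah and Alg8 were among the 11 of 13 called under PBS (84.6%, exact Clopper-Pearson interval 54.6 to 98.1). Under LPS, with Blm, Unc45a, Tsku, Ngrn, Inppl1 and Trim68 added, 15 of 17 lay there (88.2%, 63.6 to 98.5), and in the averaged comparison 21 of 26 (80.8%, 60.6 to 93.4). Fisher's exact test gave a two-sided p of 3.83e-11, 2.29e-15 and 1.74e-19. Within 1 Mb of Fes 45 genes were tested and 4, 7 and 7 were called in the 3 comparisons. Between 1 and 25 Mb from Fes 229 were tested and 7, 8 and 13 were called, all on the distal side, where 169 were tested. In the averaged comparison, over the 5-Mb windows around the calls near Fes, 77 of 201 genes (38.3%) between 80 and 105 Mb had an unadjusted p under 0.05, against 8.13% on the rest of chromosome 7 and 8.4% elsewhere. That span was set from the calls of the same comparison, and its 20 called genes are among the 77, so the excess is in part fixed by the choice. Genes of a region are not independent, so the p-values given here describe the clustering only.

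**Figure D3:**
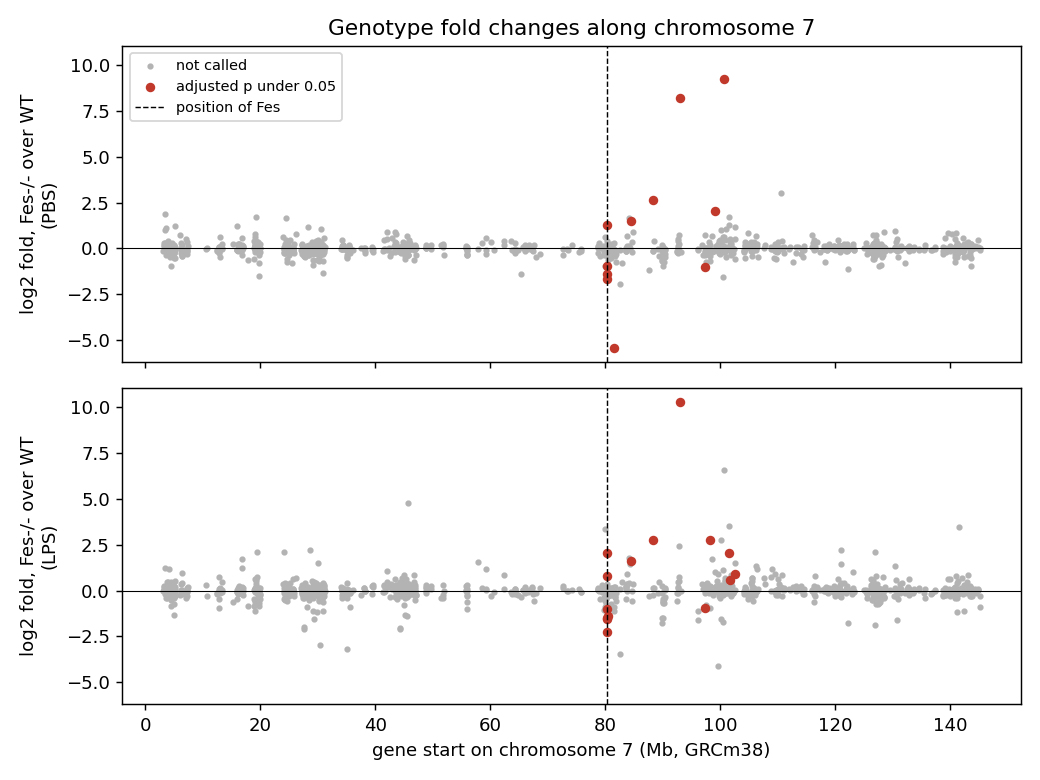
Log2 fold change of Fes-/- over wild type against gene start in Mb along chromosome 7 under PBS and LPS, 1 point per tested gene, red where the adjusted p was under 0.05 and a dashed line at Fes. The called genes lie between 80 and 105 Mb, with 11 called under PBS and 15 under LPS.

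The PBS and LPS genotype effects shared 10 called genes, all in the same direction, where independent gene lists would share 0.0075. The shared genes included Fes, Furin, Man2a2, Hddc3, Fah, Alg8 and the uncertain Amd2 and Gm44075. Both treatments drew on 3 mice per genotype, so the lists are not independent and the sharing is not a replication in other animals. Of 20 genes called under either treatment 19 had the same sign under both. Across the 15801 genes, which are not independent replicates, the fold changes had a Pearson r of 0.226 and a Spearman rho of 0.259, and Pearson's r was 0.136 over the genes called under neither treatment.

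Whether the LPS response itself differed between genotypes was tested by the interaction. Among the genes called by it Tsku changed the most, from 3.17 to 1.77 CPM with LPS in wild type and from 2.42 to 11.7 CPM in Fes-/- macrophages (interaction 3.12 ± 0.36, interval 2.34 to 3.89, adjusted p = 0.00556). Fes had an LPS effect of -1.02 ± 0.07 in Fes-/- macrophages (adjusted p = 5.67e-09) and -0.15 ± 0.07 in wild type (adjusted p = 0.0744), and the interaction was -0.87 ± 0.10 (interval -1.09 to -0.66, adjusted p = 0.00556). Unc45a rose by 1.10 ± 0.09 with LPS in wild type, its effect in Fes-/- macrophages was 0.19 ± 0.09 (adjusted p = 0.0632), and the interaction was -0.91 ± 0.13 (adjusted p = 0.0215). The LPS effects of the latter pair depended on the scale, since without a TMM factor Fes fell in wild type (-1.06) and Unc45a was at 0.19 in wild type (adjusted p = 0.0595) and -0.74 in Fes-/- macrophages. Not called were Blm (-0.75 ± 0.18), Furin (-0.55 ± 0.16), the cholesterol synthesis gene Fdps (-0.89 ± 0.30), the T-cell co-stimulator Tnfsf9 (-1.17 ± 0.42) and the IL-6 family cytokine Osm (0.59 ± 0.21), each with an adjusted p of 1. Without a filter on low counts Tnfsf9 (-1.13, adjusted p = 3.74e-10) and Blm (-0.71, adjusted p = 0.0244) were called, while over the other 21 alternatives their adjusted p ranged from 0.993 to 1 and from 0.216 to 1.

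The interaction test called these 3 genes, 1 positive and 2 negative, with 464 at an unadjusted p under 0.05 and 10507 genes (66.5%) with an interval within 2-fold. DESeq2 called 5, and 90 were called without a filter. The Unc45a interaction was lost without wild-type PBS 1, wild-type LPS 2 or 3, Fes-/- PBS 1 or 3 or any Fes-/- LPS library (adjusted p = 0.0727 to 0.122), and on TPM it was not called (0.056 and 0.0707). Fes was called for LPS in wild type without wild-type PBS 1 (0.0387), wild-type LPS 3 (0.0487) or a filter (0.0402). Unc45a was called for LPS in Fes-/- macrophages without Fes-/- PBS 3 or any wild-type PBS library (0.0192 to 0.0462). It was also called there with DESeq2 (0.0146), RLE factors (0.021) or a block for the replicate number within genotype (0.0492). Camera called 3 lists, namely cholesterol synthesis (median -0.26, 7.52e-06; adjusted p = 0.744 with an estimated correlation), Fes neighbours (-0.14, 0.000329; adjusted p = 0.0745 with an estimated correlation) and glycolysis (-0.099, 0.0058; adjusted p = 0.744 with an estimated correlation). Whatever value its member Adm takes, with 3 counts or fewer in a group, the glycolysis median lies between -0.099 and -0.095. Of the neighbours, 1 was positive and 4 negative adjusted over the list alone. The glycolysis call ended without wild-type PBS 2 (median 0.03, 0.357), Fes-/- PBS 2 (0.0715) or Fes-/- LPS 1 (0.0852) or without a filter (0.0506).

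LPS acted on most of the transcriptome in wild-type macrophages. Nos2, which makes nitric oxide, went from 0.0297 to 2630 ± 345 CPM, Il6 from 0.0144 to 1250 ± 226 CPM and Il1a from 0.272 to 5090 ± 498 CPM (n = 3 each). Ptgs2, the inducible cyclooxygenase gene, rose by 12.81 ± 0.43, the endothelial lipase gene Lipg by 14.77 ± 0.37 and the CXCR3 ligand Cxcl11 by 14.13 ± 0.31. The deepest falls were in the pro-apoptotic Bmf (-7.70 ± 0.47, from 24.1 to 0.113 CPM), Zfp395 (-7.42 ± 0.23, from 77.1 to 0.446 CPM), the stress-induced mTORC1 inhibitor Sesn1 (-7.26 ± 0.21, from 282 to 1.84 CPM), the cannabinoid receptor Cnr2 (-6.97 ± 0.14) and the chemokine receptor Cxcr4 (-6.96 ± 0.31, from 123 to 0.986 CPM).

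The edgeR test called 11601 genes in wild type, 5464 higher and 6137 lower with LPS, and 6939 of them by over 2-fold. The TMM factors averaged 1.36 under PBS and 0.723 under LPS, and without them the median of all genes moved from -0.072 to -0.98. That setting called 2579 higher and 10828 lower, so the directions of genes near 0 are relative to the TMM scale.

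All 18 NF-kB targets rose with LPS in wild type (camera adjusted p = 2.34e-32), among them the feedback inhibitor Tnfaip3 (8.29 ± 0.15) and Nfkbiz (6.63 ± 0.14). All 20 inflammatory cytokines rose (3.58e-22), such as the p28 subunit gene Il27 (9.93 ± 0.13), the T-cell and NK survival factor Il15 (4.75 ± 0.11) and Il10 (7.28 ± 0.18). Of 22 chemokines 20 rose (1.16e-13), such as Ccl3, from 8.65 to 6580 CPM. Of 20 classical activation markers 19 rose (3.32e-22). All 48 interferon-stimulated genes rose (4.41e-23; adjusted p = 0.227 with an estimated correlation), for example Irf1 (3.39 ± 0.11) and the RNA sensor Ifih1 (5.43 ± 0.20). The TMM factor did not set these directions, since without it 18, 20, 20, 19 and 48 members still rose. The counts adjusted over the list alone were the same as over all genes for these 5 lists and for the 3 lists that follow.

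Antigen presentation and co-stimulation were examined for what the T cell would meet. All 22 MHC class I genes rose with LPS (camera adjusted p = 1.24e-07; adjusted p = 0.227 with an estimated correlation), such as the immunoproteasome subunit Psmb10 (2.67 ± 0.10), the peptide transporter Tap2 (2.42 ± 0.09) and the class I transactivator Nlrc5 (3.80 ± 0.14), and without a TMM factor 14 rose and 3 fell. Of 22 co-stimulatory genes 17 rose, 3 fell and 2 were not called (2.07e-07), against 13 and 6 without the factor. Cd40 went from 8.1 to 1760 CPM (7.76 ± 0.15), the PD-1 ligand Cd274 from 23.1 to 2060 CPM (6.48 ± 0.18), and the OX40 ligand Tnfsf4 rose by 7.91 ± 0.25. MHC class II genes went both ways, with 6 up, 2 down and 5 not called (0.806), and 0 up and 8 down without the factor.

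LPS was then read in Fes-/- macrophages, where Nos2 rose by 14.45, Il6 by 16.60, Il1a by 14.45, Cxcl11 by 14.37 and Ptgs2 by 13.32, and Bmf (-7.10), Zfp395 (-7.35) and Cxcr4 (-6.45) fell. Cd40 rose by 7.55, Cd274 by 6.65, Il27 by 9.72 and Il15 by 4.86. LPS called 11574 genes, 5424 higher and 6150 lower, 6872 of them by over 2-fold. Without TMM factors, which averaged 1.39 and 0.729, the median moved from -0.083 to -1 and the calls to 2510 higher and 11064 lower. Both genotypes called 10836 genes, of which 10834 had the same sign, 765 were called in wild type alone and 738 in Fes-/- alone. Across the 12339 genes called in either, which are not independent replicates, the fold in Fes-/- on that in wild type had a slope of 0.981, a Pearson r of 0.970 and a Spearman rho of 0.981.

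**Figure D4:**
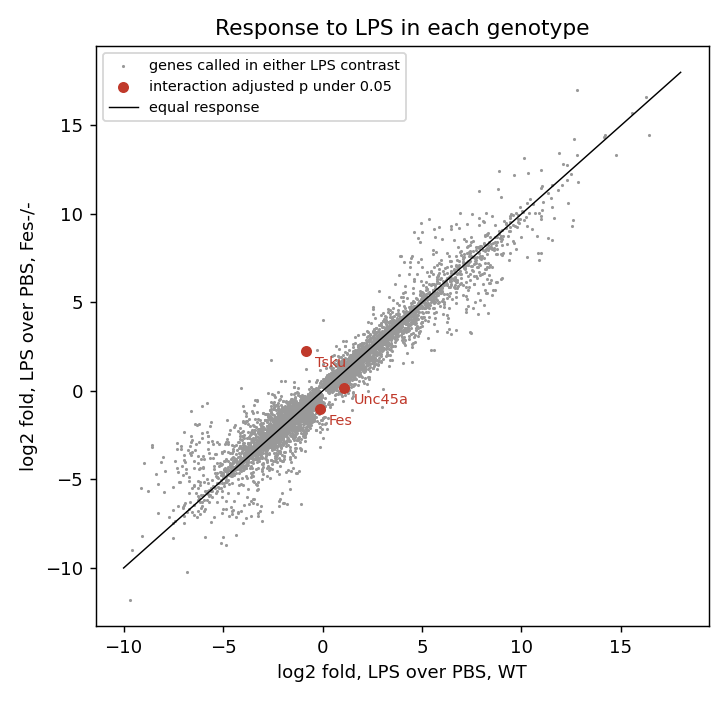
Log2 fold change with LPS in Fes-/- macrophages (y) against that in wild type (x), 1 point per gene called in either genotype, with the 3 genes called by the interaction in red. The slope was 0.981 over 12339 genes, and Tsku lies above, Fes and Unc45a below the diagonal.

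The immune lists in Fes-/- macrophages had 20 of 22 chemokines, 20 of 20 classical activation markers and 17 of 22 co-stimulatory genes higher with LPS. All interferon-stimulated and all MHC class I genes rose there too (adjusted p = 0.182 and adjusted p = 0.219 with an estimated correlation). Of the 13 MHC class II genes 6 rose, 1 fell and 6 were not called, against 1 up and 9 down without the factor. Camera called 16 of the 36 lists in wild type and 17 in Fes-/- macrophages, and 9 in each with an estimated correlation. For every list that camera called, in all comparisons, the median, the mean and the test had the same sign.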

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

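The tests of Amd2, of the chromosome 7 calls and of wild-type cells as a source of Fes reads were chosen after the result was seen. The response to LPS differed between genotypes for 3 genes and 3 lists by the interaction test. Tsku had a higher LPS effect in Fes-/- macrophages than in wild type (interaction 3.12), and Unc45a (-0.91) and Fes (-0.87) a lower one. Camera called the interaction for cholesterol synthesis (median -0.26), the neighbours of Fes (-0.14) and glycolysis (-0.099), and 0 of these lists with an estimated correlation. Of 100 splits of the libraries, 5 called at least the 3 genes of the real one, with 582 in the highest other. These splits regrouped PBS and LPS libraries separately, so a difference between genotypes or mice could appear in them as an interaction. They cannot decide whether this count arose by chance, and chance is not excluded.

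The calls on chromosome 7 reached from the neighbours Man2a2, Furin and Blm to Trim68 at 102.7 Mb, and in the averaged comparison 21 of 26 called genes lay there. The labels give no strain background for either genotype. An effect of the targeted allele within 1 Mb only would leave no calls beyond it, but 14 genes, among them Fah, Alg8, Tsku and Inppl1, were called farther away. Loss of FES acting on genes anywhere would spread the calls by gene number, but 80.8% (60.6 to 93.4) lay on chromosome 7, against 7.73% of tested genes. DNA of another strain carried along with the Fes allele may account for the span, and it stays open because no variants were read. Between 1 and 25 Mb from Fes 5.68% (3.06 to 9.51) of genes were called. These were 13 of 169 genes on the distal side and 0 of 60 on the proximal side. The range was set after the calls were seen, so this rate does not test that explanation.

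Gm44075 and Amd2 appeared in Fes-/- libraries at levels nearly absent from wild type, and each has a near-identical copy elsewhere. Gm44075 held 5.59 ± 1.3% as many counts as Trim21 under PBS and 4.36 ± 0.13% under LPS (n = 3 each), a ratio of 1.28 between treatments, while Gm44075 rose 16.1-fold and Trim21 20.5-fold with LPS in Fes-/- macrophages. Reads of Trim21, which starts at 102557921 in the called part of chromosome 7, may thus have been placed on Gm44075. The share of Amd2 in the summed Amd1 and Amd2 counts was 1.18 ± 0.66% in wild type and 39.7 ± 1.7% in Fes-/- under PBS. Under LPS it was 1.8 ± 1.2% and 38.1 ± 1.2%. In the comparison averaged over PBS and LPS, the sum of Amd1 and Amd2 had a log2 fold of 0.21 (-0.10 to 0.51). A sequence difference in Amd1 between the animals could move reads to Amd2, and a true difference in Amd2 expression was not tested.

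Fes reads remained in Fes-/- macrophages at 38.3% of wild type under PBS and 20.9% under LPS. Wild-type cells mixed into the cultures in 1 fixed share would give equal log2 folds under both treatments, but these differed by -0.87 (-1.09 to -0.66). Transcripts of the targeted allele that keep part of the gene could give such reads, but cannot be told apart from other sources, because gene-level counts hold no exons. No biological explanation of the remaining Fes reads was tested.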

How the results depend on the processing

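The counts without chromosome 7, and the use of the planned estimated correlation as an alternative to the preset one, were chosen after the result was seen. Fes, Furin, Man2a2, Alg8 and Amd2 kept direction and call in the genotype comparisons under all alternatives run. The counts of genotype calls moved, and where no construction is named the cause was not tested. DESeq2 called 33 genes under PBS, 37 under LPS, 5 for the interaction and 88 averaged, with 17 shared by PBS and LPS. Without a filter, so with many more low-count genes, these were 315, 358, 90, 581 and 113. On log2(TPM + 1) the interaction called 5 genes (10 without a filter), with slopes of 0.991 and 0.992, and log2(TPM + 0.1) gave a slope of 0.989, against 0.981. A filter of 1 CPM in 3 libraries left 3 list calls between genotypes under LPS. With an estimated correlation the list calls were 0 under PBS, 1 under LPS, 9 and 9 for LPS in wild type and Fes-/-, 0 for the interaction and 1 averaged. The fry test called 1 list under PBS, 1 under LPS, 0 for the interaction and 3 averaged, against 8, 6, 3 and 6 by preset camera. For LPS in wild type and Fes-/- it called 30 and 32, against 16 and 17. Leaving out chromosome 7 left 2, 2 and 5 genes called under PBS, LPS and averaged, since the region was removed. Under PBS and under LPS these were Amd2 and Gm44075, whose counts are uncertain. Averaged, Plagl1, Cd5l and Gm43305 came in addition, and their calls ended on leaving out single libraries. Leaving out 1 library gave 12 to 15 calls under PBS, 12 to 19 under LPS, 19 to 36 averaged, 2 to 3 for the interaction, 11074 to 11743 and 11014 to 11848 for LPS in wild type and Fes-/-, and 8 to 10 shared. Fes ranged from -1.44 to -1.35 and from -2.3 to -2.21, the slope from 0.961 to 0.998, and 94.1 to 99.5% of named calls were kept. List calls ranged from 6 to 14 under PBS, 3 to 9 under LPS, 15 to 17 and 16 to 18 for LPS, 2 to 11 for the interaction and 5 to 11 averaged. The extremes were reached without wild-type PBS 3 or Fes-/- PBS 2 (PBS lists and interaction lists) and without wild-type LPS 2 or Fes-/- PBS 3 (LPS and averaged lists). The design gives 3 mice per genotype, and the labels do not say whether same-numbered libraries come from 1 mouse. As a hint from the data, each library correlated best with its own number within its genotype (0.14 to 0.17 in wild type, 0.068 to 0.19 in Fes-/-). A block for the number gave 12, 12, 2 and 21 calls under PBS, LPS, interaction and averaged. This block also joined different mice across genotypes, where same-numbered libraries had correlations of -0.16 to 0.016, so it is not a block for the mouse. A model that fits the mouse was not run for the comparisons between genotypes. With the block for the number Fah was not called under PBS (0.122) or LPS (0.0988). Under LPS Ngrn (0.133), Inppl1 and Trim68 (0.0614 each) were not called either. The Unc45a interaction (0.0883) was lost, as were Plagl1 and Cd5l (0.137 each), Gm43305 (0.0536) and Ramac (0.0511) averaged. A block within genotype gave 11862 and 11876 calls for LPS and 4 for the interaction. Depth was 61016254 counts or more, and at 3 libraries per group under 50% of 1.414-fold changes were recovered in simulated data. That simulation made 175 calls, against 13 under PBS in the real data, so its cut-off on p was looser. Small genotype effects stay undetected, and larger differences were uncalled as well, such as Il12b under LPS (edgeR adjusted p = 0.738).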

Other observations

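The list tests with an estimated correlation and the splits of samples were planned before the data were seen. Beyond the immune lists, LPS changed metabolic and cell-biological genes in wild-type macrophages. Glycolysis genes rose, with 19 up, 3 down and 4 not called, or 19 and 3 adjusted over the list alone (camera adjusted p = 0.000604; adjusted p = 0.227 with an estimated correlation), as in hexokinase Hk2 (4.12 ± 0.13), Pfkfb3 (6.74 ± 0.20) and Hif1a (2.91 ± 0.13), but 9 rose and 12 fell without a TMM factor. Of 32 nuclear oxidative phosphorylation genes 22 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.197, and 0.00625 without a filter), as in cytochrome c, Cycs (2.45 ± 0.23), against 1 and 31 without the factor. Of 13 mitochondrially encoded genes 6 rose and 0 fell (0.684), against 0 and 7. Cell-cycle genes fell, 26 of 32 with 1 up (0.000835; adjusted p = 0.418 with an estimated correlation), and 30 without the factor, with Bub1b (-2.65 ± 0.10), Cenpf (-2.56 ± 0.17) and Aurkb (-1.64 ± 0.11) among them.

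Lipid genes went both ways. Of 23 cholesterol synthesis genes 7 rose and 8 fell, or 7 and 7 adjusted over the list alone (adjusted p = 0.717), and 3 and 15 without the factor, with Dhcr7 (-1.83 ± 0.08) and Lss (-1.39 ± 0.12) lower. Of 15 LXR targets 2 rose and 6 fell (0.148, and 0.0497 without a filter), with 0 and 11 without the factor, among them the fatty acid desaturase Scd2 (-3.32 ± 0.14). Of 28 lysosome genes 8 rose and 9 fell, or 8 and 8 adjusted over the list alone (0.922), and 1 and 25 without the factor. Their regulator Tfeb fell (-4.97 ± 0.15) and the protease Ctsc rose (2.77 ± 0.09).

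Macrophage identity genes split, with 9 up and 7 down (adjusted p = 0.98) and 3 and 16 without the factor. The granulocyte-monocyte regulator Cebpa fell (-4.62 ± 0.15), while Spi1 (1.55 ± 0.07) and the Fc receptor Fcgr1 (2.82 ± 0.13) rose. Of 17 alternative activation markers 8 rose and 5 fell (0.679), with 5 and 8 without the factor, and the fatty-acid sensor Pparg fell (-1.55 ± 0.09). Phagocytic receptors had 14 up and 4 down (0.045; adjusted p = 0.227 with an estimated correlation), with 8 and 14 without the factor, and the call ended without wild-type PBS 3 (0.0726) or wild-type LPS 2 (0.0552) or without the factor (0.0791) or with a filter of 1 CPM in 3 libraries (0.0984). Counts adjusted over the list alone were the same for these 3 lists.

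Signalling lists were mostly higher, and their counts adjusted over the list alone were the same. TLR4 components had 21 up and 8 down (adjusted p = 1.29e-06), with 14 and 15 without the factor, and Myd88 rose (3.03 ± 0.09). Inflammasome and cell death genes had 19 up and 3 down (1.01e-15), such as Nlrp3 (4.03 ± 0.09) and Cflar (4.86 ± 0.09), with 17 and 6 without the factor. Immediate-early genes had 15 up and 2 down (3.14e-07), such as Dusp2 (8.76 ± 0.15) and Junb (4.35 ± 0.12), with 12 and 5. Actin and migration genes had 27 up and 4 down (5.4e-06; adjusted p = 0.0907 with an estimated correlation), such as the integrin Itga5 (3.68 ± 0.14), with 16 and 13. FES-related kinases had 13 up and 2 down (0.000102; adjusted p = 0.0677 with an estimated correlation), such as Lyn (2.49 ± 0.09), with 9 and 6. NRF2 targets had 7 up and 9 down (0.806), with a median of -0.096 against a mean of 0.24, and 4 and 14 without the factor. The cystine transporter Slc7a11 rose (7.41 ± 0.25) and Gclc fell (-2.28 ± 0.16). Stress response genes had 8 up and 6 down (0.684), and 3 and 11 without the factor. The neighbours of Fes had 2 up, Furin among them (2.53 ± 0.12), and 6 down (0.684), and 1 and 8 without the factor.

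Among markers of other cell types only some passed the filter, and the cells that express them were not tested. Of 10 mast cell markers 2 were tested and both rose with LPS (adjusted p = 6.21e-05), with the histidine decarboxylase gene Hdc going from 0.218 to 180 CPM, but the list was not called without a filter (0.372, and 0.229 in Fes-/- macrophages). Of 14 dendritic cell markers 8 rose and 1 fell, or 7 and 1 adjusted over the list alone (0.166), with the actin bundler Fscn1 (8.35 ± 0.30) and the lymph node homing receptor Ccr7 (3.52 ± 0.32) higher, and 5 and 3 without the factor. Monocyte markers had 7 up and 2 down (0.124), such as Vcan, from 1.79 to 626 CPM, with 4 and 3. Neutrophil markers had 2 up and 2 down, or 2 and 1 adjusted over the list alone (0.725), with 2 and 7 without the factor, and Lcn2 went from 0.848 to 115 CPM. Stromal and endothelial markers had 5 up and 0 down (0.0542), and 5 and 1 without the factor, such as Cdh5 (4.31 ± 0.19). Without the factor camera called the dendritic (0.027), monocyte (0.00884) and stromal (0.0031) lists. Without a filter it called the dendritic (0.0456), monocyte (0.0313) and stromal (0.03) lists. The stromal list was also called with a filter of 1 CPM in 3 libraries (0.0169), without wild-type LPS 2 (0.0326), wild-type PBS 2 (0.0492) or Fes-/- LPS 3 (0.0456). With a block for the replicate number within genotype camera called the monocyte (0.016) and stromal (0.0114) lists in wild type. It called the monocyte list in Fes-/- macrophages too (0.0185). T and NK markers had 1 up and 1 down of 4 (0.684), with Lck going from 0.281 to 15.5 CPM, B cell markers 1 and 3 of 6 (0.765), osteoclast markers 3 and 3 of 9 (0.922) and erythroid markers 2 and 1 of 4 (0.806). Without the factor these were 1 and 3, 1 and 4, 3 and 6, and 1 and 2.

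In Fes-/- macrophages LPS gave 26 of 32 cell-cycle genes down (adjusted p = 0.00155; adjusted p = 0.415 with an estimated correlation) and 17 glycolysis genes up with 3 down (0.00221; adjusted p = 0.328 with an estimated correlation). Cholesterol synthesis had 6 up and 12 down (0.315), phagocytic receptors 15 and 3 (0.0209; adjusted p = 0.185 with an estimated correlation), and stromal markers 5 and 0 (0.0316; adjusted p = 0.328 with an estimated correlation). The stromal call ended without Fes-/- PBS 2 (0.0518) or with DESeq2 (0.0556), and the phagocytic call with a filter of 1 CPM in 3 libraries (0.0535). Without the factor 30 cell-cycle genes fell, 9 glycolysis genes rose and 16 fell, 18 cholesterol synthesis genes fell, and 8 phagocytic receptors rose and 13 fell. Adjusted over the list alone, 0 of 13 mitochondrially encoded genes were called, against 5 up over all genes.

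Xist, the only tested gene of 5 sex-linked genes, averaged 1230 ± 282 CPM in wild-type PBS, 1260 ± 191 in Fes-/- PBS, 1480 ± 121 in wild-type LPS and 1590 ± 77.3 in Fes-/- LPS libraries (n = 3 each). The 50 most abundant genes took 15.9 ± 0.5% and 15.1 ± 0.69% of counts under PBS in wild type and Fes-/- and 20.4 ± 0.34% and 20.2 ± 0.16% under LPS. The first principal component, which parted PBS from LPS, held 90% of the variance and the second 2.1%. On the second, wild-type replicate 2 scored 25.9 (PBS) and 35.2 (LPS), and Fes-/- replicate 2 -22 and -32.6.

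The libraries were also split in other ways. Under PBS 3 of 10 splits called at least the 13 genes of the real one, with 53 in the highest other, and for the other comparisons 1 of 10 did, with 17 genes under LPS, 11601 for LPS in wild type and 11574 in Fes-/- against 0 in the highest other. With 10 splits a share under 0.05 cannot be reached. In the averaged comparison 3 of 100 splits called at least 26 genes, with 582 in the highest other. Those splits moved PBS and LPS libraries separately, as if all 12 came from different mice. The design gives 3 mice per genotype, so the 12 libraries are not independent and these splits do not exclude chance. If same-numbered libraries come from 1 mouse, only 10 splits keep mice whole and a share under 0.05 cannot be reached. The split with 582 calls set wild-type replicates 1 and 2 with Fes-/- replicate 3, in both treatments, against the rest. It points to a structure of the samples that crosses the genotypes.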
